A study of Mus musculus with 6 samples.

How the data were processed

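The series holds RNA-seq of 6 HL-1 libraries, 3 with vehicle and 3 with 5 µM BRL, made from total RNA with the Illumina TruSeq RNA kit, version 2, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The 6 h of hypoxia and 1 h of reoxygenation follow the series design; the sample descriptions read ReOx7h, which was taken as the total time. The dose of 0 for vehicle was assigned here, and whether the counting used strand is not given in the sources used here. The deposited sample files hold RSEM expected counts and an RSEM fraction per gene, which sums to 1 in each library; the fraction was not used further. Per the submitters' processing notes, the tools were cutadapt, RSEM 1.17, Bowtie and edgeR and the genome build was NCBIM37; their settings are not given in the sources used here. The authors' deposited series table is named as normalised counts, but its values are log2. For 13863 of the 32739 genes they equal log2 CPM (counts scaled to the library total) with 0.5 added to each count plus a constant shift per library, with an SD around that shift of at most 0.03, and the filter behind the choice of genes is not given in the sources used here.

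Expected counts assign a read that fits several loci in part to each, so genes with near-identical copies carry more uncertain counts. Between 13.2% and 15.6% of expected counts per library were not whole within 0.005, and named genes with such counts are marked as not whole, so their values are less certain. Total expected counts ranged from 4440168 to 8332472 per library, and 3 counts, the floor used for a gene with no counts, correspond to 0.360 to 0.676 CPM. Symbols were matched to gene identifiers through the supplied table of names (88.4% of all genes and 96.9% of tested genes). The reference at hand, GENCODE M21, belongs to another build, so it was used only for symbols, transcript length, GC content, exon overlap and matching transcripts, and no coordinates are given. Matches to genes with no counts in 1 group were sought with BLAST 2.17.0 at 97% identity over at least 100 bases.

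Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM library factors, quasi-likelihood F-test with group as the only term). Adjusted p-values follow Benjamini and Hochberg over the 12047 genes kept, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. Before the data were examined, 27 gene lists were fixed: adrenergic receptors and cyclic AMP machinery, nitric oxide and cyclic GMP pathway, CREB targets and immediate early genes, hypoxia and HIF targets, glycolysis, apoptosis regulators, mitochondrial permeability transition, unfolded protein and integrated stress responses, NRF2 and antioxidant genes, heat shock, NFκB targets and cytokines, interferon response, p53 targets, cardiomyocyte and atrial genes, PPAR and fatty acid oxidation, sterol synthesis, cell cycle, circadian clock, extracellular matrix and TGFβ targets, nuclear oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, and markers of fibroblasts, endothelium, smooth muscle and leukocytes. The 23 lists with at least 5 tested members were tested two-sided with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over these lists. Beside it, camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a direction, were run.

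The genes named follow a rule fixed before the data were examined. In each direction, up to 10 genes with a symbol were taken by absolute log2 fold change among those past the threshold with a mean of at least 1 CPM and no overlap between groups; a gene with no symbol was named by its identifier and not counted against the 10. To these were added Adrb1, Adrb3, Nos1, Nos2 and Nos3, up to 4 members of smallest p for each list past camera, and the member of smallest p for each other list. Some genes that the rule takes are not reported here. Pde4d, Gem, Fn1, Mybpc3, Gja1, Casq2, Nppa, Rpl8 and Rps21 lie outside the rule and were chosen after their values were seen.

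Libraries of a group were compared by chi-square over genes with at least 10 counts in a pair. The statistic per degree of freedom was 1.69 to 3.95 among vehicle libraries, 4.20 between BRL replicates 2 and 3, and 89.1 and 76.8 between BRL replicate 1 and those, so no pair agreed within sampling noise. The test was tried on simulated counts of the 12047 genes for this comparison, with 50 genes changed at each size. It recovered 16 genes at 1.5-fold, 32 at 2-fold, 48 at 4-fold and 48 at 8-fold, and 18 unchanged genes made up 11.0% of the 163 calls, above the nominal 5%. A shift of 0.3 (log2) given to the ribosomal protein list was called and no other of the 23 lists was. Simulated genes were drawn independently of each other. In the data the correlation estimated within a list reached 0.997, for mitochondrially encoded genes. The simulation therefore does not show how often lists are called falsely here. Each simulated gene had the same spread in all libraries, while in the data BRL replicate 1 stood apart from the others. The numbers of genes recovered and the 11.0% may therefore not hold for the data.

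Alternatives set before the data were examined were RLE and upper-quartile factors, no filter, CPM over 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, edgeR's exact test, the replicate number as a block, and leaving out each library. Alternatives added after the data were examined were limma on the deposited log2 table, mitochondrially encoded genes left out, library totals with no further factor, each library's trend on transcript length and GC content removed (mgcv 1.9.3, with and without the block, and without BRL replicate 1), limma-voom with library quality weights, and counts thinned to the smallest library. Camera with an estimated correlation was also run with each library left out, likewise added. Figures were drawn with matplotlib 3.10.9.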

Results

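Messenger RNA was sequenced from HL-1 cells, a mouse line derived from atrial cardiomyocytes that keeps part of the contractile gene programme in culture. The cells went through 6 h of hypoxia and 1 h of reoxygenation, a cell model of ischaemia and reperfusion, and received 5 µM of BRL, which the series describes as an agonist of the β3-adrenergic receptor, or vehicle in the culture medium. When BRL was added relative to hypoxia and reoxygenation is not stated in the sources used here. Each group had 3 libraries. Total expected counts were 4440168, 4872948 and 5060049 in vehicle replicates 1, 2 and 3 and 6812810, 7516242 and 8332472 in BRL replicates 1, 2 and 3, so that depth did not overlap between the groups. Nothing states that the libraries of a group came from separate cultures, and p-values therefore measure the spread between these samples, which may be technical.

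The comparison asked which transcripts differed with the agonist after hypoxia and reoxygenation. Among genes higher in BRL, Nr4a3, an orphan nuclear receptor and immediate early gene, went from 4.91 ± 1.00 to 29.9 ± 2.90 CPM (SD, n = 3 in each group). Pde4b, a phosphodiesterase that degrades cyclic AMP, went from 37.8 ± 2.83 to 98.7 ± 8.65 CPM, and Kdr, the main signalling receptor for VEGF, from 6.19 ± 2.37 to 44.6 ± 8.25 CPM. Myh6, Ldb3 and Pln, genes of the fixed cardiomyocyte list, were lower. Myh6, the α-myosin heavy chain, went from 3336 ± 306 to 1329 ± 321 CPM, Ldb3, a Z-disc protein, from 295.1 ± 14.7 to 116 ± 10.1 CPM, and Pln, the inhibitor of the sarcoplasmic calcium pump, from 195.0 ± 21.1 to 68.02 ± 8.21 CPM.

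By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 122 of 12047 genes rose and 216 fell with BRL at adjusted p under 0.05. Of these, 40 rose and 76 fell by at least 2-fold. In all 338 genes, every library of 1 group lay above every library of the other. Among all genes tested, 15.97% had every BRL library above and 15.5% every BRL library below, where chance gives 5% in each direction. Expected counts were not whole numbers for 52 of the genes that rose and 67 of those that fell, so part of their reads was shared with other loci.

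**Figure D1:**
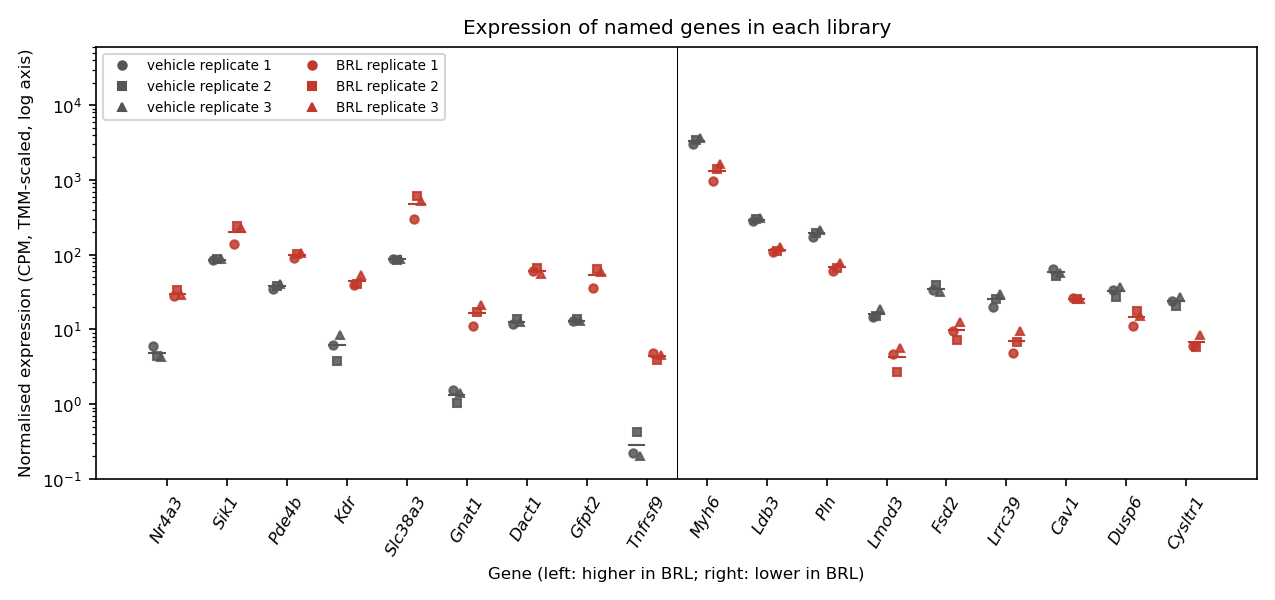
Normalised expression (CPM, TMM-scaled, log axis) of 9 genes higher and 9 genes lower in BRL, in each of the 3 vehicle (grey) and 3 BRL (red) libraries. Symbols mark the replicate and bars the group mean; for each gene the 2 groups do not overlap.

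Among the genes with the largest rises, Tnfrsf9, a receptor of the tumour necrosis factor family, had a log2 fold change of 3.87 ± 0.42 (SE, edgeR adjusted p = 0.00404) at 4.41 ± 0.42 CPM in BRL. In vehicle Tnfrsf9 had 1, 2 and 1 counts, under the floor of 3, so the size of its rise is uncertain. Gnat1, the α subunit of rod transducin, rose by 3.61 ± 0.34 (adjusted p = 0.00265) and Kdr by 2.84 ± 0.25 (adjusted p = 0.00189). Nr4a3 rose by 2.61 ± 0.18 (adjusted p = 0.000693). Slc38a3, a glutamine transporter, rose by 2.46 ± 0.24 from 86.3 ± 2.28 to 476 ± 161 CPM (adjusted p = 0.00294). Dact1, a regulator of Wnt signalling, rose by 2.25 ± 0.13 (adjusted p = 0.000629), although its exons overlap those of another annotated gene. Gfpt2, an enzyme of the hexosamine pathway, rose by 2.01 ± 0.23 (adjusted p = 0.00492).

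The largest falls among genes detected in both groups had log2 fold changes between −1.90 and −1.68. They included Lmod3 (−1.90 ± 0.26), a nucleator of sarcomeric actin, and Fsd2 (−1.84 ± 0.20). Lrrc39, an M-band protein, had −1.84 ± 0.25, with counts that were not whole and exons that overlap another gene. Cysltr1, a receptor for cysteinyl leukotrienes, had −1.81 ± 0.19, and Pla2g4e, a phospholipase, −1.79 ± 0.37 at 2.62 ± 0.16 against 0.743 ± 0.185 CPM. Xkr4 had −1.68 ± 0.36. Scd4, Gm10874, Lrp2bp and ENSMUSG00000091746, a gene with no symbol, had −1.90, −1.79, −1.76 and −1.88, and the counts of these genes were not whole. The edgeR adjusted p of all these genes lay between 0.00391 and 0.0479. Among the fits that left out a library, Gm10874, Pla2g4e, Lrp2bp and Xkr4 passed only in the fit without BRL replicate 1.

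In 4 genes past the threshold, every library of 1 group had no counts, and their expected counts were not whole. Against a floor of 3 counts per library, Gm20721 was at least 24.0-fold, Gm6055 at least 7.11-fold and Gm14303 at least 3.55-fold higher in BRL, and Gm5884 was at least 11.4-fold lower. Each has a transcript that matches a more abundant gene, which is Gnas, Map1lc3b, Rps29 and Tom1 in that order, all with counts that were not whole. Summed with their matching genes, the log2 differences between the group means were 0.09, 0.31, 0.49 and 0.05.

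The receptor addressed by the agonist was near the detection limit. Adrb3 had 3, 0 and 1 counts in the vehicle libraries and 3, 4 and 5 in the BRL libraries, where the floor of 3 counts corresponds to between 0.360 and 0.676 CPM, and a difference was not detectable at this depth. Adrb1, the β1-adrenergic receptor, measured 11.97 ± 1.48 CPM in vehicle and 23.6 ± 12.9 CPM in BRL and did not pass the test (log2 fold change 0.98 ± 0.42, edgeR adjusted p = 0.214). Without BRL replicate 1, which had 9.13 CPM, the log2 fold change of Adrb1 was 1.37 with adjusted p = 3.0e-05, and over 21 alternatives its adjusted p ranged from 3.0e-05 to 0.472. Of the nitric oxide synthases, Nos1 had a log2 fold change of −0.09 ± 0.53 (adjusted p = 0.944), and Nos2 and Nos3, with at most 4 and 8 counts in any library, fell below the filter on low counts; counts of Nos1 and Nos3 were not whole.

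Of 24 tested genes for adrenergic receptors and the cyclic AMP machinery, 2 rose and none fell. These were Pde4b (log2 fold change 1.38 ± 0.11, edgeR adjusted p = 0.00169) and Pde4d (1.23 ± 0.22, adjusted p = 0.0293), which both encode cyclic AMP phosphodiesterases; adjusted over the list alone, 2 rose and 1 fell. The list as a whole did not pass camera (adjusted p = 0.0812), and it did without BRL replicate 1 (adjusted p = 0.0260, and 0.416 with an estimated correlation). In that fit 7 members rose and 2 fell, and the median log2 fold change was 0.004, so the call rested on part of the list. Among 35 CREB targets and immediate early genes, 4 rose and 1 fell, and adjusted over the list alone 10 rose and 2 fell. Nr4a3, Sik1 (1.24 ± 0.19), Gadd45a (1.06 ± 0.21) and Gem (0.63 ± 0.12) rose, and Dusp6, a phosphatase that inactivates ERK, fell from 32.7 ± 4.93 to 14.5 ± 3.12 CPM. The list was higher as a set by camera (adjusted p = 0.000134), with adjusted p = 0.534 with an estimated correlation (unadjusted p = 0.337). Its median level over the vehicle mean was 0.00, 0.65 and 0.26 (log2) in BRL replicates 1, 2 and 3, and without BRL replicate 2 it did not pass (adjusted p = 0.150). In the fit without BRL replicate 1, 18 members rose and 2 fell. Of 19 genes of the nitric oxide and cyclic GMP pathway, Cav1, the main protein of caveolae, fell (−1.18 ± 0.11, edgeR adjusted p = 0.00265) and 18 did not pass; adjusted over the list alone 3 fell.

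Of 43 cardiomyocyte and atrial genes, 6 fell and 1 rose, and adjusted over the list alone 16 fell and 2 rose. Pln (log2 fold change −1.52 ± 0.13, edgeR adjusted p = 0.00183), Ldb3 (−1.34 ± 0.10, adjusted p = 0.00145), Myh6 (−1.33 ± 0.19, adjusted p = 0.0117), Mybpc3 (−0.80 ± 0.12), Gja1 (−0.73 ± 0.11) and Casq2 (−0.62 ± 0.10) fell. The counts of Myh6 and Nppa were not whole, and the exons of Pln and Myh6 overlap another annotated gene. The atrial peptide gene Nppa did not pass (492 ± 33.9 against 472 ± 55.6 CPM, adjusted p = 0.803). The list was lower as a set by camera (adjusted p = 1.3e-07), with adjusted p = 0.534 with an estimated correlation (unadjusted p = 0.0828). Its median level was −0.81 in BRL replicate 1 and −0.21 and −0.24 in BRL replicates 2 and 3, and that of 8 smooth muscle markers was −1.11, −0.23 and −0.23 in the same libraries. Without BRL replicate 1 the median log2 fold change of the cardiomyocyte list went from −0.40 to −0.17, and 19 members fell and 8 rose. In that fit its camera adjusted p was 4.0e-06, and 0.416 with an estimated correlation. With the length and GC trend also removed its median was −0.28 (camera adjusted p = 4.4e-10, and 0.293 with an estimated correlation).

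**Figure D2:**
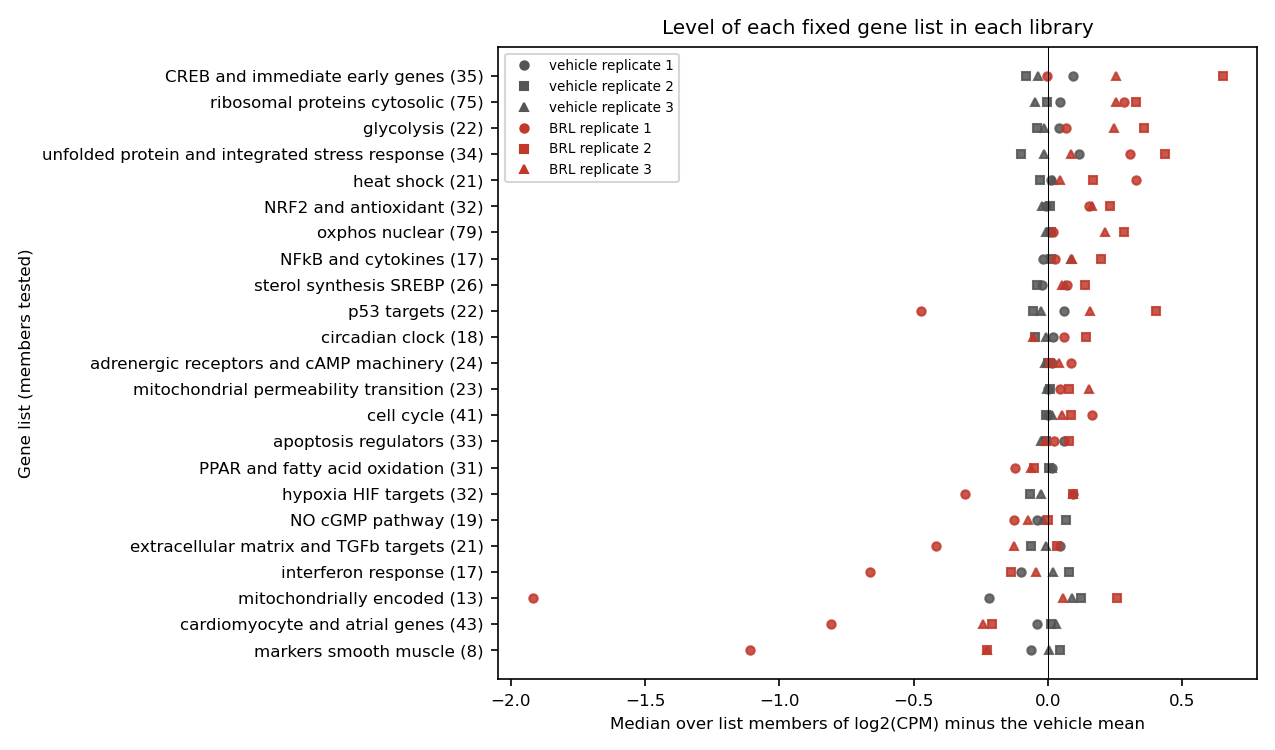
Median over the tested members of each fixed gene list of log2(CPM) minus the vehicle mean, in the 3 vehicle (grey) and 3 BRL (red) libraries, with symbols for the replicate. BRL replicate 1 lies at −1.92 for mitochondrially encoded genes and −0.81 for cardiomyocyte and atrial genes, and the 3 BRL libraries lie between 0.25 and 0.33 for ribosomal proteins.

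Cytosolic ribosomal protein genes were higher in all 3 BRL libraries, with list medians of 0.28, 0.33 and 0.25 (log2) over the vehicle mean. Of 75 tested, 10 rose and none fell, and adjusted over the list alone 38 rose and 1 fell. Rpl28 (log2 fold change 0.70 ± 0.10), Rps27a (0.63 ± 0.12), Rps15 (0.51 ± 0.10) and Rps7 (0.49 ± 0.09) were among those that rose, with edgeR adjusted p between 0.0123 and 0.0385. Leaving out BRL replicate 1, 50 rose and 1 fell. Counts were not whole for 65 of the 75, these 4 included, and 2 of the 10 that rose, Rpl8 and Rps21, had whole counts. The median log2 fold change was 0.31 over all 75 and 0.31 over the 10 with whole counts. The list was higher by camera (adjusted p = 2.5e-13), with adjusted p = 0.534 with an estimated correlation (unadjusted p = 0.0487). None of 79 nuclear genes of oxidative phosphorylation passed the edgeR test over all genes, 5 rose adjusted over the list alone, and without BRL replicate 1, 37 rose and none fell. The list was higher by camera (adjusted p = 2.3e-05), with adjusted p = 0.534 with an estimated correlation (unadjusted p = 0.234), and had a median of 0.16. In this list 26 genes had an unadjusted p under 0.05, and DESeq2 called 3, the exact test 7 and limma-voom 0. Its level was 0.02 in BRL replicate 1 against 0.28 and 0.21 in replicates 2 and 3. Cyc1 had the smallest p of this list (0.42 ± 0.09, edgeR adjusted p = 0.0529).

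By camera with the preset correlation, 4 further lists were higher. They were the unfolded protein and integrated stress responses, NRF2 and antioxidant genes, glycolysis and heat shock (adjusted p of 1.3e-05, 0.00746, 0.0191 and 0.0263). With an estimated correlation each had adjusted p = 0.534, from unadjusted camera p of 0.233, 0.0239, 0.348 and 0.291. The correlation estimated for the NRF2 list was −0.02, below the preset 0.01, so correlation between its genes is not what raised its p. Of 34 genes of the unfolded protein and integrated stress responses, none passed edgeR over all genes and 8 rose adjusted over the list alone; 12 had an unadjusted p under 0.05, and DESeq2 called 6, the exact test 8 and limma-voom 0. Cebpb had a log2 fold change of 1.01 ± 0.23, Sdf2l1 of 0.61 ± 0.15 and Calr of 0.49 ± 0.13, with edgeR adjusted p between 0.0589 and 0.0881. Of 32 NRF2 and antioxidant genes, mitochondrial thioredoxin Txn2 rose (0.54 ± 0.11, adjusted p = 0.0386), and adjusted over the list alone 3 rose and 1 fell. Of 22 glycolysis genes, the lactate transporter Slc16a1 rose (0.52 ± 0.10, adjusted p = 0.0404), and adjusted over the list alone 7 rose and 3 fell. None of 21 heat shock genes passed edgeR, over all genes or adjusted over the list alone; 8 had an unadjusted p under 0.05, and DESeq2 called 2, the exact test 2 and limma-voom 0. Without BRL replicate 1, members that rose numbered 14, 14, 14 and 6 in these 4 lists in the order given, and 1, 1, 3 and 1 fell. The glycolysis list did not pass without vehicle replicate 2, BRL replicate 2 or BRL replicate 3 (adjusted p of 0.0577, 0.150 and 0.0581), and the heat shock list did not without vehicle replicate 2 or BRL replicate 1 (0.0577 and 0.174).

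In 3 other lists that did not pass as sets, 1 or 2 members passed. Of 18 circadian genes Nfil3 rose (log2 fold change 1.08 ± 0.21, edgeR adjusted p = 0.0352), and of 17 interferon response genes Ifit2 fell (−0.70 ± 0.13, adjusted p = 0.0328). Of 21 extracellular matrix genes and TGFβ targets, Fn1, the fibronectin gene, rose (0.72 ± 0.14) and Tgfb3 fell (−1.42 ± 0.28, adjusted p = 0.0379). Counts of Gadd45a, Txn2, Fn1 and Cebpb were not whole. Exons of Gadd45a, Pla2g4e, Tgfb3, Adrb3, Nos1, Nos3, Cebpb, Rpl28, Rps27a, Lrp2bp, Gm10874, Gm20721, Tgm2, Bak1 and Ddr2 overlap another annotated gene. Adjusted over the list alone, 1 circadian gene rose, 1 interferon gene rose and 2 fell, and 3 matrix genes rose and 4 fell. No member passed over all genes among 32 hypoxia and HIF targets, 33 apoptosis regulators, 23 genes of the mitochondrial permeability transition, 17 NFκB targets and cytokines, 22 p53 targets, 31 PPAR and fatty acid oxidation genes, 26 sterol synthesis genes or 41 cell cycle genes. Adjusted over the list alone, 2 PPAR genes fell, 5 cell cycle genes rose and 2 fell, and in the other 6 of these lists none passed. The members of smallest p in 7 of these lists, the sterol list apart, were Tgm2, Bak1, Mfn2, Nfkb1, Aen, Pdk4 and Rrm2, with edgeR adjusted p between 0.0612 and 0.09996, and counts of Tgm2, Bak1 and Pdk4 were not whole. Over the 225 places in these 8 lists, 56 had an unadjusted p under 0.05, and DESeq2 called 7, the exact test of edgeR 17 and limma-voom 0; without BRL replicate 1, 49 rose and 27 fell. By camera the p53 targets had adjusted p = 0.712, and without BRL replicate 1 the list passed (adjusted p = 0.000238, and 0.507 with an estimated correlation) and 10 of 22 members rose. The NFκB list passed without BRL replicate 1 (adjusted p = 0.0408), the interferon list without BRL replicate 2 or 3 (0.0388 and 0.0156) and the matrix list without BRL replicate 2 (0.0388); with an estimated correlation these adjusted p were 0.507, 0.698, 0.577 and 0.698.

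Transcripts encoded in mitochondria took 16.5%, 20.2% and 19.7% of counts in the vehicle libraries and 5.03%, 21.9% and 20.0% in BRL replicates 1, 2 and 3, with Wilson 95% intervals no wider than 0.1 percentage points that cover counting error only. None of the 13 mitochondrially encoded genes passed edgeR, over all genes or adjusted over the list alone, none had an unadjusted p under 0.05, and DESeq2, the exact test and limma-voom called 0; without BRL replicate 1 edgeR called 0. The list had a median log2 fold change of −0.27 (camera adjusted p = 0.148) and, without BRL replicate 1, of 0.16 (adjusted p = 0.0408, and 0.696 with an estimated correlation). Without BRL replicates 2 and 3 in turn it was lower by camera with the preset correlation, with adjusted p of 0.00456 and 0.0342, and 0.698 and 0.636 with an estimated correlation. Of markers of other cell types, 8 smooth muscle genes were lower as a set by camera (adjusted p = 0.0226). With an estimated correlation this list had adjusted p = 0.534 (unadjusted p = 0.347). None of its genes passed singly by edgeR, and 3 had an unadjusted p under 0.05. DESeq2, the exact test and limma-voom called 2, 0 and 0. Without BRL replicate 1, 4 fell. Acta2 measured 2651 ± 177 CPM in vehicle and 1677 ± 574 CPM in BRL (edgeR adjusted p = 0.164). Without BRL replicate 1 the smooth muscle list did not pass camera (adjusted p = 0.0696). With the length and GC trend also removed it passed (camera adjusted p = 0.00826, and 0.416 with an estimated correlation). Of 4 endothelial markers above the filter Kdr rose, of 2 fibroblast markers Ddr2 had a log2 fold change of −0.40 ± 0.12 (adjusted p = 0.102), and Cd68, the leukocyte marker above the filter, had 0.08 ± 0.39 (adjusted p = 0.930). Of 4 replication-dependent histone genes, Hist1h1c had 0.35 ± 0.19 (adjusted p = 0.313). Counts of Acta2, Ddr2 and Hist1h1c were not whole.

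Of the named genes past the threshold with all libraries, the 14 that passed in each of the 6 fits that left out 1 library were Nr4a3, Kdr, Gnat1, Slc38a3, Dact1, Pde4b, Gm20721, Gm6055, Cav1, Ldb3, Pln, Fsd2, Cysltr1 and ENSMUSG00000091746, and 11, among them Gadd45a, Slc16a1, Txn2 and Nfil3, passed in the fit without BRL replicate 1 and in no other of the 6. Without BRL replicate 1, 1240 genes rose and 1315 fell, which included all 338. Leaving out vehicle replicate 1, 2 or 3 gave 22, 20 and 17 genes that rose and 34, 28 and 15 that fell, and leaving out BRL replicate 2 or 3 gave 43 and 45 that rose and 84 and 103 that fell.

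**Figure D3:**
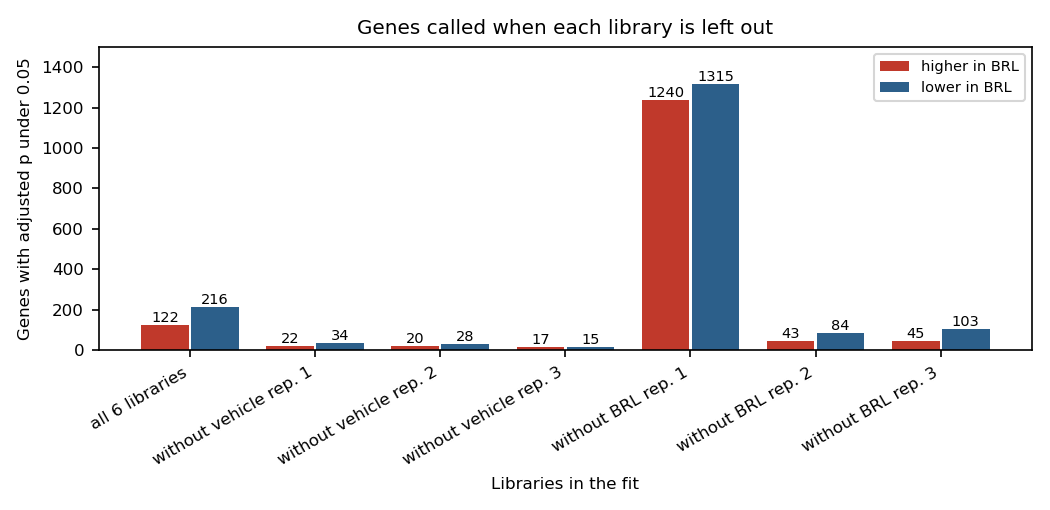
Number of genes higher (red) and lower (blue) in BRL at an edgeR adjusted p under 0.05 with all 6 libraries and with each library left out. Bars start at 0 and carry their counts; the fit without BRL replicate 1 reaches 1240 and 1315 genes against 122 and 216 with all libraries.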

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

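The alternatives with the deposited log2 table, mitochondrially encoded genes left out, library totals only, the length and GC trend removed, library quality weights and thinned counts were chosen after the data were examined. The 2 fits planned on log2(value + 1) and log2(value + 0.1) of the deposited table were not run, because its values are already log2. No gene past the threshold with all libraries (122 higher, 216 lower) changed sign in any alternative, and the median log2 fold change of all genes stayed within 0.05 of 0. With no filter 282 genes were higher and 330 lower, with DESeq2 242 and 350, with edgeR's exact test 418 and 527, and with library quality weights 1128 and 1215; library totals only gave 77 higher. Leaving out 1 library gave 17 to 1240 genes higher and 15 to 1315 lower, the high ends without BRL replicate 1 and the low ends without vehicle replicate 3. With the length and GC trend also removed, the fit without BRL replicate 1 gave 811 higher and 793 lower. Of list members, 32 passed in the main fit, 73 with no filter, 86 with DESeq2, 109 with the exact test, 267 with quality weights and 6 to 296 with 1 library left out. The replicate block gave 63 genes higher, against 122, and 150 lower; deviations of same-numbered libraries correlated at 0.10, −0.02 and −0.02, so the numbers were not taken to pair the samples. Of 75 named genes tested none reversed; 22, 23 and 25 lost the call without vehicle replicate 1, 2 and 3, 13 and 15 without BRL replicate 2 and 3, 10 under the block and at most 6 in any other alternative, and 32 gained it without BRL replicate 1. Of the lists, 7 were higher and 2 lower by camera, 11 higher with no filter, and 0 and 0 with an estimated correlation. With fry, a test of each list on its own, 3 were higher (ribosomal proteins, NRF2, permeability transition) and 1 lower (PPAR). The permeability transition and PPAR lists had medians of only 0.04 and −0.03 in the main fit, with camera adjusted p of 0.292 and 0.375. Leaving out 1 library gave 1 to 5 lists lower, quality weights 1, and the length and GC trend removed with the replicate block 4. The median of mitochondrially encoded genes was −0.27 in the main fit, 0.16 without BRL replicate 1, −0.60 without BRL replicate 2 (the range with 1 library left out) and 0.26 without BRL replicate 1 with the length and GC trend also removed, so its sign depended on BRL replicate 1. Apart from fewer libraries or more genes tested, the cause of these changes was not tested. Depth limits genes near the floor, among them Adrb3, Nos2, Nos3 and, in vehicle, Tnfrsf9.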

Other observations

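The slope of BRL replicate 1, the ribosomal protein medians without that library, over genes with whole counts and with thinned counts, and the count of splits for genes were tests chosen after the result was seen, and the fits with mitochondrially encoded genes or the length and GC trend removed were added after the data were examined. The genes in the next 2 paragraphs were chosen after their values were seen.

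Further genes rose. Igf1, insulin-like growth factor 1, went from 34.1 ± 2.12 to 94.8 ± 2.55 CPM (log2 fold change 1.48 ± 0.10, edgeR adjusted p = 0.000693), Vdr, the vitamin D receptor, from 70.5 ± 4.56 to 212 ± 18.1 CPM and Irs2, an adaptor of the insulin and IGF receptors, from 21.2 ± 0.27 to 64.8 ± 13.8 CPM. Arrdc3, an arrestin-like protein that binds adrenergic receptors, rose by 1.52 ± 0.16 (edgeR adjusted p = 0.00391), Npr3, the natriuretic peptide clearance receptor, by 0.97 ± 0.11 and Dio2, the deiodinase that makes active thyroid hormone, by 1.45 ± 0.31. Gnat1 and Slc38a3, which both rose, are neighbours in the RefSeq gene table of assembly GRCm38.

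Further genes outside the fixed cardiomyocyte list fell. Nexn, an actin-binding Z-disc protein, went from 421 ± 14.8 to 178 ± 45.1 CPM (log2 fold change −1.24 ± 0.17, edgeR adjusted p = 0.00979), and Trim55 had −1.24 ± 0.13, Smyd1 −1.05 ± 0.13, Nebl −0.95 ± 0.12, Trdn −0.91 ± 0.16 and Myom1 −0.68 ± 0.10. Hif1a fell by 0.63 ± 0.12 on the log2 scale (edgeR adjusted p = 0.0370), while none of the 32 hypoxia and HIF targets passed the test. Counts of Irs2, Dio2, Nebl and Hif1a were not whole.

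BRL replicate 1 stood apart from every other library, with a mitochondrial share of 5.03%, a quality weight of 0.128 against 0.933 to 1.96 in the others, and 338 genes called with it against 2555 without it. With the mitochondrially encoded genes removed, 326 genes were called. The TMM factors already allow for their share of counts, so removing them could change little, and what lowered that share was not tested. With each library's trend on transcript length and GC removed, 309 genes were called, against 1604 without BRL replicate 1. The trends therefore do not account for the whole gap. A vehicle library under a BRL label is argued against by a slope of 0.71 across genes of its differences on those of BRL replicates 2 and 3, from separate vehicle libraries (0.82 and 0.81 with other vehicle libraries). BRL replicates 2 and 3 share trends on length (Spearman −0.37 and −0.30 across genes, which are not independent) and GC (0.41 and 0.32) that BRL replicate 1 lacks (0.14 and −0.12). The vehicle libraries lie at 0.11 to 0.16 and −0.22 to −0.14, so on these trends BRL replicate 1 sits with vehicle, which goes with a wrong label where the slope does not. Without BRL replicate 1 the removal of both together took the calls from 2555 to 1604; neither was removed alone. RNA quality, the state of the culture and an outside sample stay open, and the larger number of calls may in part reflect these shared trends.

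The rise of ribosomal protein genes was seen in all 3 BRL libraries. Removing the length and GC trends left the list median at 0.26, from 0.31, and without BRL replicate 1 it was 0.29. These values argue against the trends or that library as the whole cause. With counts thinned to the smallest library the median was 0.30. Thinning leaves the expected ratios between libraries unchanged, and depth did not overlap between the groups, so a difference tied to depth stays open. With BRL replicate 1 left out and the trends removed together the median was 0.17 (camera adjusted p = 6.4e-07, and 0.510 with an estimated correlation, against 0.534 with all libraries and the trends kept), so the trends may account for part of the rise. Counts of 65 of the 75 genes were not whole, but the 10 genes with whole counts, 9 of them positive, had a median of 0.31 (SD 0.19 between genes), which argues against reads shared between copies as the whole cause. The nuclear oxidative phosphorylation list had a median of 0.13 after the trends were removed, from 0.16. Without BRL replicate 1 its median was 0.25, and 0.11 with the trends also removed, so the trends may account for part of its rise too. A part played by shared reads in the 65 genes, differences in RNA quality or library preparation, and an effect of the agonist were not tested and stay open.

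Of the genes with no counts in 1 group and past the threshold, 4 of 4 had family sums that differed by under 0.5 (log2). Each gene was small beside that sum with its matching genes. Gm20721, Gm6055 and Gm14303 had 15.7, 4.60 and 2.26 CPM of 524, 147 and 191 CPM in BRL. Gm5884 had 4.51 of 70.6 CPM in vehicle. The sums would barely move even if the genes themselves changed, so they cannot decide whether reads were assigned to a different copy. Genes with no counts on 1 side and at least 3 in each library of the other numbered 7 in the real split of the 6 libraries and 1 to 8 in the other splits. Sequence differences between the HL-1 line and the reference were not tested.

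Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, gave as many as 338 genes, and the highest other gave 0. For gene lists, 3 of the 10 splits gave as many as the real split's 9, and the highest other gave 10. The ribosomal protein list had camera adjusted p = 2.5e-13 in the real split and 1.2e-06 to 0.53 in the others. For the cardiomyocyte and atrial list these were 1.3e-07 and 0.00015 to 0.77. With 10 splits the share cannot fall under 0.05.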
